A study of Mus musculus with 1000 samples.

How the data were processed

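The series is part of a screen of mice whose founder males, of the C57BL/6NCrl strain, received 3 doses of 100 mg/kg of N-ethyl-N-nitrosourea (ENU), a chemical that causes point mutations. Per the labels' protocols, generation 3 mice of 8 to 12 weeks were collected, usually 12 siblings per pedigree, and RNA was taken from the brain without the cerebellum. Each cDNA reaction started from 4 ng of total RNA and was amplified for 8 cycles with a 3' end kit. The cDNAs of the 12 wells of 1 plate row each carried their own in-line index and were pooled before the sequencing adapters were added, so that 12 plates gave 96 pools and a library of 1152 samples. GSNAP and the build GRCm38 are named in the submitters' processing notes, with no version of the aligner. The gene counter is not given in the sources used here.

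The file analysed here is a lookup table that the authors deposited. It has 3 columns and 23231 rows: a row number, a library name and the part of a larger deposit that holds the library. The name and part columns hold text only, and no column is a measurement of expression. All 1000 libraries of the series were found in it by an exact match of the title, and 22231 rows belong to libraries outside the series and were not used beyond counting them. Expression values of these libraries were not analysed here, so sequencing depth is unknown, and the tests of expression between genotypes that had been planned before the lookup table was opened were not run. The rule for named genes therefore leaves only the genes of the labels: Smpd1, Postn, Idua and Med12l. The gene lists planned for an expression table were not used.

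What remained was the design. Groups came from the candidate, genotype and phenotype labels of each library. In these, m/m, m/+ and +/+ mark the genotype at the candidate variant. They were read here as homozygous mutant, heterozygous and homozygous reference. A blank phenotype was counted as carrying no phenotype label. It does not show that the mouse was scored and found unaffected. Library titles were split into a prefix, a mouse number, a plate letter and column, a plate name and a number after S. The labels do not define these parts. The prefix was read as the pedigree, and the letter as the plate row, because the letters run from A to H and the columns from 1 to 12. The parts of the title were used for counts of libraries and prefixes per plate row and plate, and for plate columns. They were also used for runs of mouse numbers and for matching candidate labels to prefixes.

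Within each of 3 pedigrees with genotypes, the presence of a phenotype label other than unaffected, which describes the labels and not how often a phenotype occurred, was compared between m/m mice and all others with the two-sided Fisher's exact test. These tests were fixed before the lookup table was opened but after the labels had been read. Genotype counts were compared with 1:2:1, the ratio from a cross of 2 heterozygotes, with an exact multinomial test, and p-values were adjusted by the Benjamini-Hochberg method over the 3 pedigrees at a threshold of 0.05. The 3 pedigrees were also combined by shuffling phenotype labels within each pedigree, evaluated exactly and one-sided. Plate columns were compared by an exact two-sided permutation test, and genotype counts between pedigrees by a permutation test with 100000 resamples. The share of m/m mice has an exact Clopper-Pearson 95% interval, which covers counting error only and treats the siblings as independent. The candidate codons were located in GENCODE release M21, which is on GRCm38, the build named in the submitters' notes. Coding exons were joined from the annotation, translated, and checked for the labelled reference residue. Positions are 1-based. Python 3.11.15, SciPy 1.17.1 and matplotlib 3.10.9 were used. The multinomial test was checked against the binomial test and on simulated 1:2:1 crosses. The adjustment and the plate column permutation were run on small examples with known answers. The other tests were not checked in this way. Alternatives were the set of genotypes compared with m/m, DAM as the only phenotype counted, an expected ratio of 1:4:3, the m/m share alone against 1/4, and leaving out each mouse or each pedigree in turn.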

Results

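The screen searched brain RNA of ENU-mutagenised mice for abnormal inflammatory states and used exome sequences to find candidate causal variants. The series comprised 1000 brain RNA libraries, whose titles fell into 84 prefixes read as pedigrees. Of these, 82 had 12 libraries each, and the others had 10 and 6. The labels marked 70 libraries, from 6 pedigrees, as an annotated subset. The remaining 930 libraries carried no group and entered no comparison. Expression was not analysed here, because the deposited table names libraries and holds no expression values. The results are therefore the genetics and the layout of the annotated pedigrees.

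Of the 6 annotated pedigrees, 4 carried a candidate missense variant. The genes were Smpd1, which encodes the lysosomal enzyme acid sphingomyelinase, Idua, which encodes the lysosomal enzyme alpha-L-iduronidase, Postn, which encodes the extracellular matrix protein periostin, and Med12l, which encodes a Mediator subunit. The other pedigrees were labelled Paralysis and Unaffected, with 12 libraries each and no genotype. A genotype was given for 35 libraries, a phenotype for 15 and a histology block for 9. The phenotype given most often was DAM, in 12 mice. The labels do not spell DAM out; in this field it usually stands for disease-associated microglia.

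All 4 variants could be placed in coding exons of GRCm38, and the labelled reference residue was found at each position. Smpd1 (ENSMUSG00000037049.9) spans chromosome 7 from 105554360 to 105558389 on the plus strand. The codon of C248S lies in exon 2 of 6, at 105555657 to 105555659, and reads TGT. Idua (ENSMUSG00000033540.18) spans chromosome 5 from 108660331 to 108684557 on the plus strand. The codon of E130V lies in exon 5 of 15, at 108679709 to 108679711, and reads GAG. Postn (ENSMUSG00000027750.16) spans chromosome 3 from 54361109 to 54391037 on the plus strand. The codon of N158K lies in exon 5 of 22, at 54369173 to 54369175, and reads AAT. Med12l (ENSMUSG00000056476.13) spans chromosome 3 from 59005825 to 59318682 on the plus strand. The codon of L1939I lies in exon 38 of 44, at 59275999 to 59276001, and reads CTT. The reference residue was present in all coding transcripts searched for Smpd1 (1), Idua (3) and Postn (4). For Med12l it was at this position in 1 of 5 coding transcripts, Med12l-206, so that the numbering holds for that isoform.

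**Figure D1:**
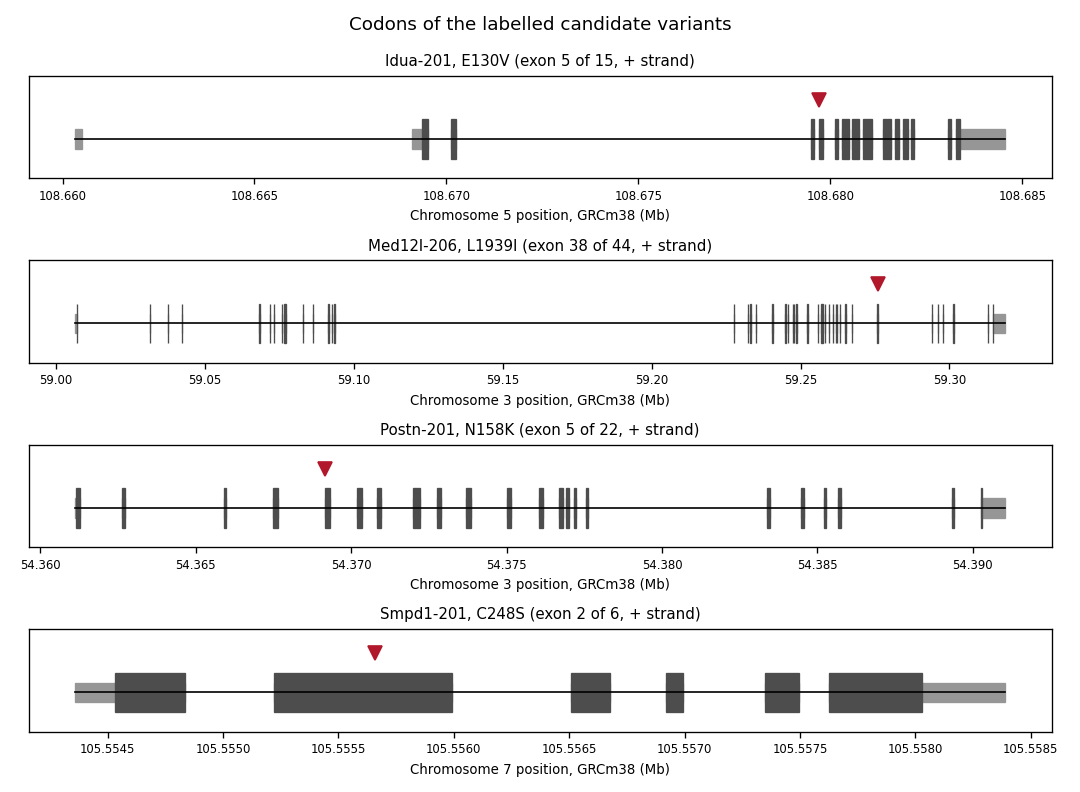
Exon maps of the transcripts used for the 4 candidate variants, with the genomic position in Mb (GRCm38) on the x axis. Tall dark boxes are coding sequence, low grey boxes are untranslated exon sequence and the red triangle marks the codon, which lies in exon 2 of Smpd1, exon 5 of Idua, exon 5 of Postn and exon 38 of Med12l.

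The first comparison asked how completely the phenotype label went together with the genotype at the candidate variant. Across the Smpd1, Idua and Postn pedigrees, all 12 m/m mice were labelled DAM, and none of 10 m/+ and 12 +/+ mice carried that label. Of these 22 others, 1 m/+ mouse of the Idua pedigree was labelled unaffected and 21 had no phenotype given, so the tests compare which mice carry the label and not how often the phenotype occurred. In the Smpd1 C248S pedigree the label was given to 9 of 9 m/m mice and to 0 of 3 others (two-sided Fisher's exact p = 0.00455, adjusted p = 0.0136). In the Idua E130V pedigree it was given to 2 of 2 m/m mice and to 0 of 8 others (exact p = 0.0222, adjusted p = 0.0333), and leaving out either m/m mouse gave an adjusted exact p of 0.111, the smallest that 1 against 8 mice allows, with the labels still fully separated. Against +/+ mice alone, which are 1 in the Smpd1 and 4 in the Idua pedigree, the adjusted exact p was 0.125 in both, with the labels again fully separated among mice too few to pass the threshold. In the Postn N158K pedigree it was given to the 1 m/m mouse and to 0 of 11 others, where the exact p of 0.0833 is the smallest that this pedigree allows. The unadjusted exact p-values of the Smpd1 and Idua pedigrees are likewise the smallest that their counts allow, since the labels were fully separated. With labels shuffled within pedigrees, the exact one-sided p over the 3 pedigrees was 8.42e-06, again the smallest that the counts allow. The labels do not say whether the phenotype was called before the genotype was known, and the screen looked for variants that fit the phenotype, so these p-values are not independent evidence of a cause.

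**Figure D2:**
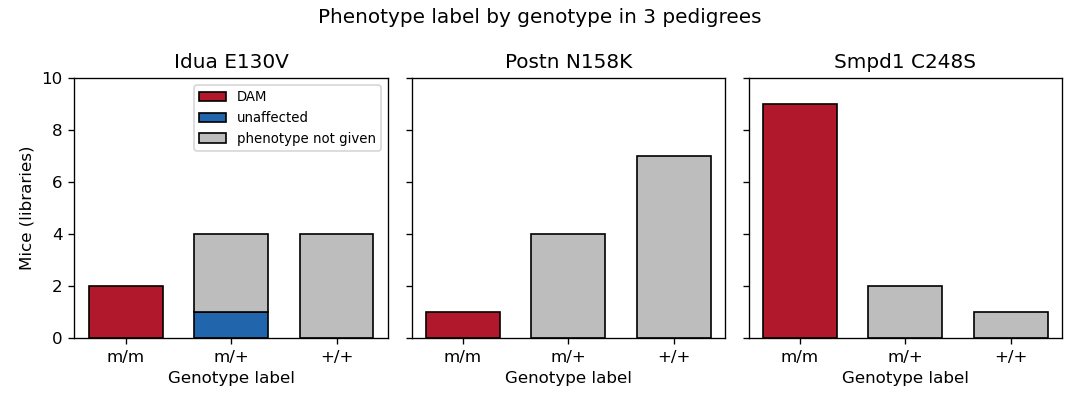
Number of mice (y axis, 1 library each) by genotype label (x axis) in the Idua, Postn and Smpd1 pedigrees, with bars divided by phenotype label. The 12 mice labelled DAM all stand in the m/m bars, with 2 in the Idua, 1 in the Postn and 9 in the Smpd1 pedigree.

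The Med12l L1939I pedigree could not be compared in this way. A genotype was given for 1 of its 12 mice, which was m/m and carried the phenotype label for a high MG signature or density. Another mouse, with no genotype, was labelled Peripheral Myeloid, and the other 10 had neither label.

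Genotype counts differed between the pedigrees. The Smpd1 pedigree had 9 m/m, 2 m/+ and 1 +/+ mice, so that 75% were m/m (95% interval 42.8% to 94.5%). This departed from 1:2:1 (exact multinomial p = 0.000992, adjusted p = 0.00298). Its mouse numbers, as read from the titles, formed 2 runs. Mice 14 to 19, in plate columns 7 to 12, were all m/m (6 of 6), and mice 22 to 27, in columns 1 to 6, had 3 m/m, 2 m/+ and 1 +/+. The Postn pedigree had 1 m/m, 4 m/+ and 7 +/+ mice, and its departure did not pass the threshold after adjustment (exact p = 0.0467, adjusted p = 0.0701). That call rests on single mice and on the assumed cross: the adjusted exact p ran from 0.0138 to 0.175 without 1 mouse, under the threshold in 5 of 12 runs, and was 0.538 against 1:4:3. The Idua pedigree had 2 m/m, 4 m/+ and 4 +/+ mice among the 10 included (exact p = 0.603). The 3 sets of counts differed from one another in a test that reassigned mice to pedigrees (permutation p = 0.00597, 100000 resamples). This test treats siblings as independent and as exchangeable between pedigrees. Genotype counts depend on the parents of each pedigree, which the labels do not name, so the p does not measure variation between crosses.

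Pedigrees were also compared with the pooling of libraries. Among the libraries of the series, 83 of the 84 prefixes lay within 1 plate row and 1 was spread over 2 rows. Each of the 85 rows held 1 prefix of the series. All 12 columns were filled in 81 rows, and libraries outside the series were not checked for the remaining wells. Since the 12 wells of a row were pooled before adapters were added, pedigree and pool cannot be told apart in a comparison between pedigrees. Mice of different genotype in the Smpd1, Idua and Postn pedigrees shared their row. Within the row of the Smpd1 pedigree, m/m mice had a mean plate column of 7.44 and the others of 3.67, a difference that did not pass the threshold (exact permutation p = 0.145). Columns 7 to 12 of that row held m/m mice only, so this p does not show an even layout. In the Idua pedigree the mean columns were 5.50 and 6.75 (exact permutation p = 0.756). In the Postn pedigree the m/m mouse was in column 5 and the others had a mean of 6.64 (exact permutation p = 0.833). The 6 annotated pedigrees lay on 4 plates. The Unaffected pedigree shared its plate with the Postn pedigree and with none of the other 4, and the Smpd1 pedigree shared its plate with the Paralysis pedigree.

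A histology block was recorded for 4 m/m mice of the Smpd1 pedigree, in block 4. The Idua and Postn pedigrees shared block 3, which held 2 m/m mice and the unaffected m/+ mouse of the Idua pedigree and the m/m mouse of the Postn pedigree. In the Med12l pedigree, 1 mouse with no genotype or phenotype label was in block 6. No histology block of the Smpd1 or Postn pedigree had a recorded sibling of another genotype among these libraries.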

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

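With m/m compared with +/+ mice alone, the adjusted exact p became 0.125 in the Smpd1, Idua and Postn pedigrees, so that the calls of the Smpd1 and Idua pedigrees were lost. With so few mice this comparison cannot reach the threshold. Counting DAM alone is the same test in these pedigrees, which have no other phenotype label than unaffected. Alternatives chosen after seeing the data left out each mouse from the comparison of phenotype labels, and each pedigree. Without 1 mouse the adjusted exact p ran from 0.0182 to 0.0333 in the Smpd1 pedigree and from 0.0417 to 0.111 in the Idua pedigree, where 0.111 is the smallest p that 1 m/m mouse against 8 allows. In the Postn pedigree it was 0.0909, and no value exists without its m/m mouse. Over the pedigrees together, leaving out 1 pedigree gave exact p-values from 0.000101 to 0.00185. Each of these is the smallest that the remaining counts allow, since the labels stayed fully separated. They reflect the number of mice and are no check on the separation itself. For the genotype counts, the Smpd1 pedigree stayed past the threshold against 1:4:3 (adjusted exact p = 3.44e-06), for the m/m share alone (0.00117) and without each mouse (0.000993 to 0.00826). The Postn pedigree gave 0.538 against 1:4:3 and 0.474 for the m/m share alone. Without 1 mouse it ran from 0.0138 to 0.175, and passed without its m/m mouse (0.0138) or any of its 4 m/+ mice (0.0290). The Idua pedigree ran from 0.457 to 0.908 without 1 mouse, and it passed under none of the settings. With candidate labels in place of title prefixes, 6 of 6 labels had 1 prefix each. Matching by accession found 0 of the 1000 libraries, as the table lists titles only. Other settings for expression (normalization, filter, pseudocount, block) were not run. No paired analysis was possible because replicate numbers only count mice within a group and no expression values were tested.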

Other observations

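The tests in this part were chosen after the labels had been seen. Two-sided tests of phenotype label by genotype within each pedigree and of the m/m share against 1/4 were fixed before the lookup table was opened. The one-sided binomial test and the one-sided test over the pedigrees together were not among these fixed tests. The labelled protein changes can be set against the reference codons, with positions counted from 1 at the first base of the codon. In Idua, E130V is reached by 1 base change, A2T. In Med12l, L1939I is reached by 1 base change, C1A. In Postn, N158K is reached by T3A or T3G, and in Smpd1, C248S by T1A or G2C. A change at an A or T base is thus required for the Idua and Postn variants and possible for the Smpd1 variant, if each is a change of 1 base. For the Med12l variant it is excluded under the same condition, but only if the label follows the numbering of Med12l-206.

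The excess of m/m mice in the Smpd1 pedigree is a pattern to follow up. An m/m parent shared by all 12 mice is argued against by the 1 +/+ mouse, and chance in 1 cross of 2 heterozygotes taken without regard to genotype by a one-sided exact binomial p of 0.000392. Choice of this variant as the most enriched of many cannot be told apart from a true departure, because the number screened is not in the labels: the chance of a count this high is 0.0324 over 84 pedigrees with 1 variant each, and 0.532 over the about 1936 sets of 12 that the 23231 libraries of the lookup table would make. Different parents for the mice of the 2 runs of mouse numbers also stay open, with 6 of 6 against 3 of 6 m/m, since the two-sided Fisher's exact p of 0.182 is the smallest that these counts allow and the labels name no parents. No biological explanation was tested.

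A second pattern is that DAM stood with m/m mice alone, while 21 of the 22 other mice had no phenotype given. Within these pedigrees, library pool does not separate mice that carry the label from mice that do not, because each pedigree lay within a single plate row. In 3 of 3 pedigrees, mice with and without the label shared that row. This is a feature of the layout and not a test that could have come out otherwise. Whether the phenotype itself followed the pool cannot be told, because 21 of the 22 other mice had no phenotype given. Choice of the variant to match the phenotype cannot be told apart from an effect of the variant, because the p of 8.42e-06 assumes a variant chosen without the phenotype, and no mice genotyped after that choice are marked. An effect of the Smpd1, Idua or Postn variant stays open and untested, as does a linked variant on the same chromosome.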
